A study of Homo sapiens with 10 samples.

How the data were processed

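RNA was sequenced from the human liver cancer cell lines Huh7, PLC and 97H, named as in the labels, treated with vehicle (control), a CDK4/6 inhibitor, an XPO1 inhibitor or both. Total RNA was taken with Trizol and made into libraries with a TruSeq RNA kit; doses, times and batches are not given in the sources used here. The 10 libraries are 1 per line and treatment, so the replicate is the cell line: replicates 1, 2 and 3 of control and of the CDK4/6 inhibitor are Huh7, PLC and 97H, and replicates 1 and 2 of the XPO1 inhibitor and of the combination are PLC and 97H. Pairing by line was taken from the labels and checked: the log2 deviations of control and CDK4/6 inhibitor libraries from their group means, across genes, had a Pearson r of 0.901 in Huh7, 0.665 in PLC and 0.818 in 97H, and the log2 values of libraries correlated at 0.9215 to 0.9798 within a line and 0.6842 to 0.7996 between lines. No pair of libraries had identical values.

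Per the submitters' processing notes, bases were called with CASAVA 1.8.2, reads aligned with STAR 2.4.2g1 to GRCh38 and counted with featureCounts of Subread, whose version is not given. The deposited table holds FPKM computed by the authors for 20030 genes in the 10 libraries; the notes do not say how FPKM was obtained from the counts, and no scaling between libraries is named. In 27 entries the gene symbol had been turned into a date and was restored from the accession beside it. Whole reads could not be recovered from FPKM, so no count model was run and the absolute depth is unknown. The smallest nonzero values place the relative depth of the libraries between 0.866 and 1.14 of that of the PLC combination library (lowest in the PLC control, highest in the Huh7 control), an estimate resting on 5.66% to 17.1% of the low genes, and 14033 to 15264 genes were above 0 FPKM per library. The sum of FPKM, 321388 to 377933, does not measure depth.

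Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend of variance on expression, two-sided) on log2(FPKM + 1) for the 10477 genes with a mean of at least 1 FPKM over the 10 libraries, with cell line as a block. The pseudocount of 1 shrinks the log2 differences of genes at low FPKM. The CDK4/6 inhibitor against control used all 10 libraries (4 residual degrees of freedom); the XPO1 inhibitor and the combination against control, the combination against each inhibitor, and the interaction used the 8 libraries of PLC and 97H (3 residual degrees of freedom). p-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison, and an adjusted p under 0.05 was called. The same filter keeps some genes that are at 0 FPKM in all 8 of those libraries, and the filter taken over the 8 libraries was tried beside it.

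The comparisons, tests, filter, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each comparison the rule takes up to 10 genes up and 10 genes down with the largest absolute log2 fold change among called genes that changed the same way in every line, leaving out entries without a gene symbol; where fewer passed, the smallest p among genes with 1 direction in every line fills the places, and these did not pass. It adds the target and reference genes and, from each list described, 2 to 4 members with the smallest p. There are 25 gene lists: target and reference genes; DNA replication and S phase; G2 and mitosis; homologous recombination repair; secretory phenotype of senescent cells; NF-kappaB target genes; lysosome; CRBN and cullin-4 ubiquitin ligase; proteasome; nuclear transport receptors and Ran; ribosome biogenesis and MYC; interferon-stimulated genes; antigen presentation by MHC class I; cholesterol synthesis; hepatocyte function; integrated stress response; endoplasmic reticulum chaperones; heat shock; polyadenylated histone genes; extracellular matrix; hypoxia and glycolysis; nuclear genes of oxidative phosphorylation; mitochondrially encoded genes; and markers of other cell types. Of the 25, 24 had at least 5 tested members, and the mitochondrially encoded genes are not in the table. The results of 1 further list, of 1 target and reference gene and of 1 marker gene are not given here. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated and with fry. Some genes stand in more than 1 list. Reads of near-identical histone genes cannot be assigned with certainty to 1 gene.

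Within each line, differences are log2 ratios of FPKM + 1 to the control of that line, without a test. The median of a list was set among 10000 random lists matched on expression, and the responses of lines were compared by Spearman correlation across genes. Gene positions, transcript GC content and length came from GENCODE 29 on GRCh38, matched for 19178 of the 20030 entries (95.7%) and for 10412 of the 10477 tested genes (99.4%). After the data had been seen to follow GC content, each library was also corrected for GC content and length. Its log2 deviations from the gene means over the libraries were regressed on natural splines (4 degrees of freedom each) of both, and the fitted trend was removed. That correction, its form with GC content alone, and its repeats without the PLC control and without the 97H CDK4/6 inhibitor library were chosen after seeing the data, and so were the filter over the 8 libraries and the fits of all 10 libraries without PLC or without 97H. The other alternatives were a pseudocount of 0.1, no filter and a filter of 5 FPKM, quantile and median ratio scaling, no block, all 10 libraries in the model, a single prior variance, a least log2 change of 1, and each library or line left out.

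The tests were tried on simulated data of the same design with 200 changed genes among 10412 in each of 5 runs. With 3 lines, 72.8% of changes of 1 and 100% of changes of 2 on the log2 scale were found, and 29% and 100% when GC content trends like those of the libraries were left in. With 2 lines it was 36.4% and 99.7%, and 6.57% and 98.2% with the trends left in. After the correction 36.1% and 99.7% were found, but this was fixed in advance and does not test the correction. The trends put in were those that the same correction had fitted to these libraries. The noise was drawn independently for each gene, with the spread left after the correction, so the shares may not hold for these libraries. Of the calls, 3.91% to 7.32% were false. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 did the remaining steps. Samples of other kinds were not analysed here.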

Results

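RNA was sequenced from 3 human liver cancer cell lines, named Huh7, PLC and 97H in the labels, after vehicle, a CDK4/6 inhibitor, an XPO1 inhibitor or both. CDK4 and CDK6 are the cyclin D kinases that phosphorylate RB1, and XPO1 carries proteins and RNAs out of the nucleus. The titles name the XPO1 inhibitor as KPT330 (selinexor) and give no name for the CDK4/6 inhibitor. There are 10 libraries, 1 for each line and treatment: 3 controls, 3 with the CDK4/6 inhibitor, 2 with the XPO1 inhibitor and 2 with the combination. Huh7 has the control and the CDK4/6 inhibitor only. The series concerns senescence under the combination and the response to drugs that recruit the ubiquitin ligase substrate receptor CRBN. Each difference was tested with limma on log2(FPKM + 1), FPKM being fragments per kilobase of transcript scaled to the mapped fragments of a library. The standard errors rest on the spread of treatment effects between lines, pooled over all treatments in a fit and moderated over genes. They are not the spread of 1 difference alone. If no gene changed, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05. The limma counts given below for the XPO1 inhibitor against control, the combination against each inhibitor and the interaction lie under that share.

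With the combination, genes that drive DNA synthesis and mitosis fell in both PLC and 97H. BIRC5 (survivin, a chromosomal passenger and apoptosis inhibitor) fell by 3.64 on the log2 scale (SE 0.37, adjusted p = 0.0176, n = 2 lines), from 90.36 to 3.633 FPKM in PLC and from 82.37 to 9.588 FPKM in 97H. The mitotic kinase gene PLK1 fell by 3.27, and the transcription factor genes MYBL2 and FOXM1, which drive cell-cycle genes, by 3.41 and 2.97. The nucleotide synthesis genes RRM2 and TYMS fell by 3.52 and 3.30. CENPA (the centromeric histone), KIF2C (a mitotic kinesin), CCNA2 (cyclin A2) and LMNB1 (lamin B1, a nuclear lamina protein that is low in senescent cells) fell by 3.06, 3.01, 3.02 and 2.89. Genes that rose include MYL9 (a myosin light chain) at 3.41, from 75.15 to 484.4 FPKM in PLC and from 4.205 to 91.77 FPKM in 97H. CYR61 and CTGF, matrix-associated YAP target genes, rose by 2.95 and 2.58. UBD (a ubiquitin-like modifier), DUSP15 (a phosphatase), FSTL3 (an activin antagonist), TMEM140, RND1 (a small GTPase), TRPM4 (a cation channel) and HIST1H2AC (a histone H2A) rose by 3.49, 3.23, 3.06, 2.95, 2.80, 2.71 and 2.57. The standard errors of these 20 genes run from 0.32 for CYR61 to 0.51 for UBD. In GRCh38, 3 of these genes lie at chromosome 17, 78214186 to 78225636 (BIRC5), chromosome 16, 23677656 to 23690367 (PLK1) and chromosome 20, 36541484 to 36551447 (MYL9). In all, 83 of 10477 tested genes changed against control, 32 up and 51 down, each of the 83 in the same direction in both lines. At the level of single tests 1301 had an unadjusted p under 0.05. The count is 0 without the PLC control or the PLC combination library, 2 without the 97H combination library, 166 without the 97H control, 158 without the PLC CDK4/6 inhibitor library and 184 without the 97H one. In each of these fits the treatment of the missing library keeps 1 library, and the spread comes from the other treatments. Without the cell line in the model the count is also 0, with no filter on low genes 1 and with a single prior variance 27. It is 153 with quantile normalization, 261 with all 10 libraries in the model, and 576 (260 up, 316 down) after removal of GC content and length trends.

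**Figure D1:**
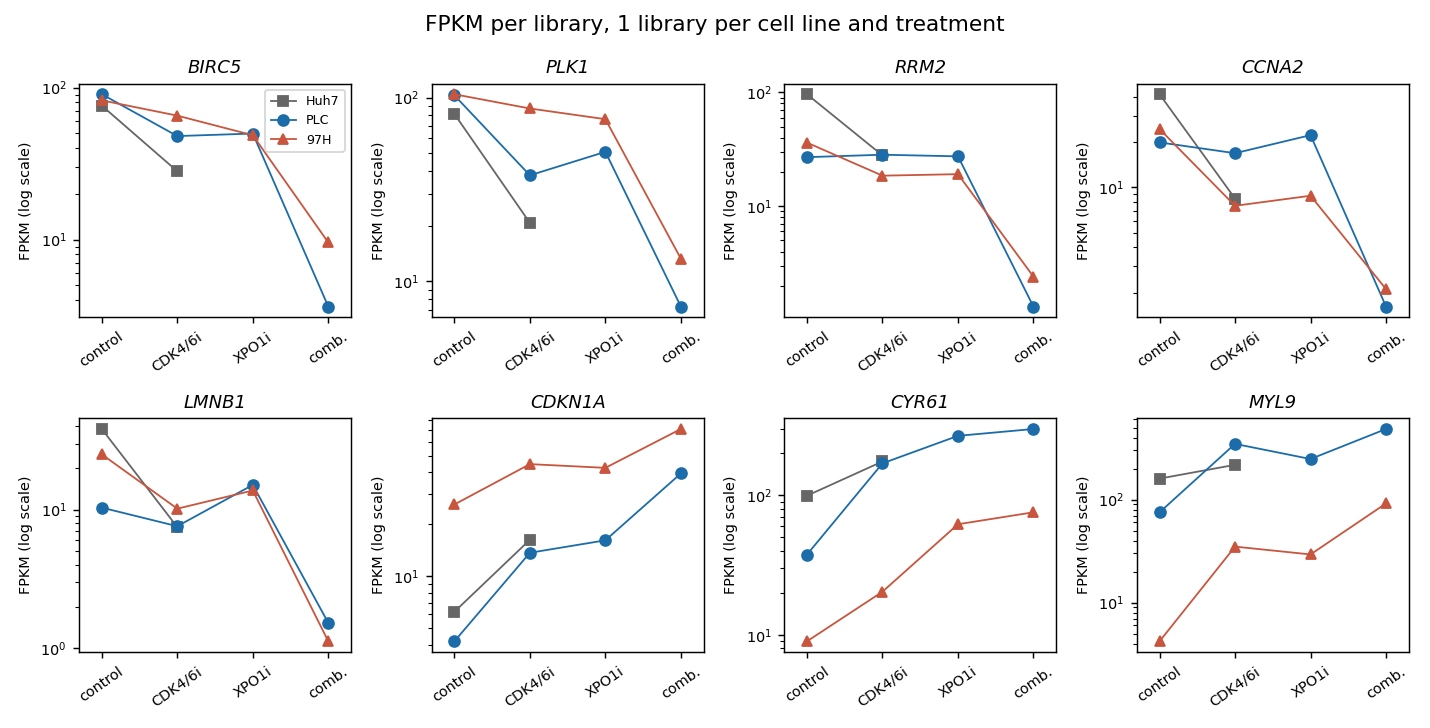
FPKM on a log axis of BIRC5, PLK1, RRM2, CCNA2, LMNB1, CDKN1A, CYR61 and MYL9 against treatment, 1 point for each of the 10 libraries, with lines joining the libraries of a cell line. BIRC5 lies at 3.633 FPKM in the PLC combination library and 9.588 FPKM in the 97H one, against 90.36 and 82.37 FPKM in their controls.

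Lists of mitosis and DNA replication genes had the smallest camera p under the combination. Of 30 tested genes of G2 and mitosis 12 fell, BIRC5, PLK1, FOXM1 and UBE2C (-2.75) among them, and 29 fell when adjusted over the list alone. The list median was -2.09 in PLC and -2.29 in 97H (camera, adjusted p = 4.6e-35, but adjusted p = 0.125 with an estimated correlation). Of 41 genes of DNA replication and S phase 14 fell, and 30 when adjusted over the list alone, with RRM2, TYMS, GINS2 (-2.82) and ASF1B (-2.45) at the smallest p (camera, adjusted p = 3.48e-34; adjusted p = 0.112 with an estimated correlation). None of 12 genes of homologous recombination repair passed over all genes and 6 fell when adjusted over the list alone, RAD54L at -1.67 and EXO1 at -1.77 having the smallest p (camera, adjusted p = 2.42e-07; adjusted p = 0.246 with an estimated correlation). Among 30 genes of ribosome biogenesis and MYC only FBL (fibrillarin, an rRNA methyltransferase, -1.81) fell, and BOP1 was at -1.58 (camera, adjusted p = 2.42e-07, and adjusted p = 0.246 with an estimated correlation). The shift of this list was mostly that of 97H, its median being -0.98 there and -0.16 in PLC. After removal of the GC content and length trends it was -0.93 and -0.19. Proteasome genes were lower by a median of -0.40, with PSMC3 at -0.95 and none of 31 passing (camera, adjusted p = 2.6e-05; adjusted p = 0.125 with an estimated correlation). camera compares a list with all other genes at a preset correlation of 0.01, and none of its 73 list calls over the 6 comparisons passed with the correlation estimated from these libraries. fry, which compares a list with no other genes, tests by its directional p whether the members move one way on balance and by its mixed p whether they change in either direction. It called 3 and 18 lists over the 6 comparisons, and its directional adjusted p was 0.022 for DNA replication and S phase under the combination against control.

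Lysosomal, matrix and histone genes stood on the upper side under the combination. Lysosomal genes had a median of 1.04 in PLC and 0.74 in 97H, with NPC2 (cholesterol egress, 1.36), ATP6V0E1 (a proton pump subunit, 1.21) and PSAP (prosaposin, 1.13) at the smallest p (camera, adjusted p = 1.14e-10; adjusted p = 0.179 with an estimated correlation). None of the 32 passed over all genes and 14 rose when adjusted over the list alone. The histone genes with polyadenylated transcripts had a median of 2.37 in PLC and 1.19 in 97H. Of the 12, HIST1H1C (2.36) and HIST1H2AC rose (2.57), HIST1H3D being at 2.20, and adjusted over the list alone 9 rose and 1 fell (camera, adjusted p = 2.81e-09; adjusted p = 0.246 with an estimated correlation). In the extracellular matrix list CYR61 and CTGF rose, 2 of 21 and 4 when adjusted over the list alone, with TGFBI at 1.62 (camera, adjusted p = 2.42e-07; adjusted p = 0.125 with an estimated correlation). Of 28 genes of the secretory phenotype of senescent cells TIMP2 (a metalloproteinase inhibitor) rose, by 2.52, the only one also when adjusted over the list alone, with HBEGF at 1.54 and CXCL1 at 1.32 (camera, adjusted p = 0.000442; adjusted p = 0.246 with an estimated correlation). NF-kappaB target genes had a median of 0.39 with none of 23 passing, CXCL1 and ICAM1 (0.95) leading (camera, adjusted p = 0.00662; adjusted p = 0.38 with an estimated correlation). Markers of other cell types were higher, none of 5 passing (camera, adjusted p = 0.0198, and adjusted p = 0.37 with an estimated correlation). KRT7 was at 1.40 and LUM at 1.37 over both lines, mostly through 97H. There KRT7 went from 5.23 to 34.6 FPKM and LUM from 3.17 to 26 FPKM. In PLC both were low, KRT7 going from 0.0378 to 0.269 FPKM and LUM from 0 to 0.0306 FPKM.

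**Figure D2:**
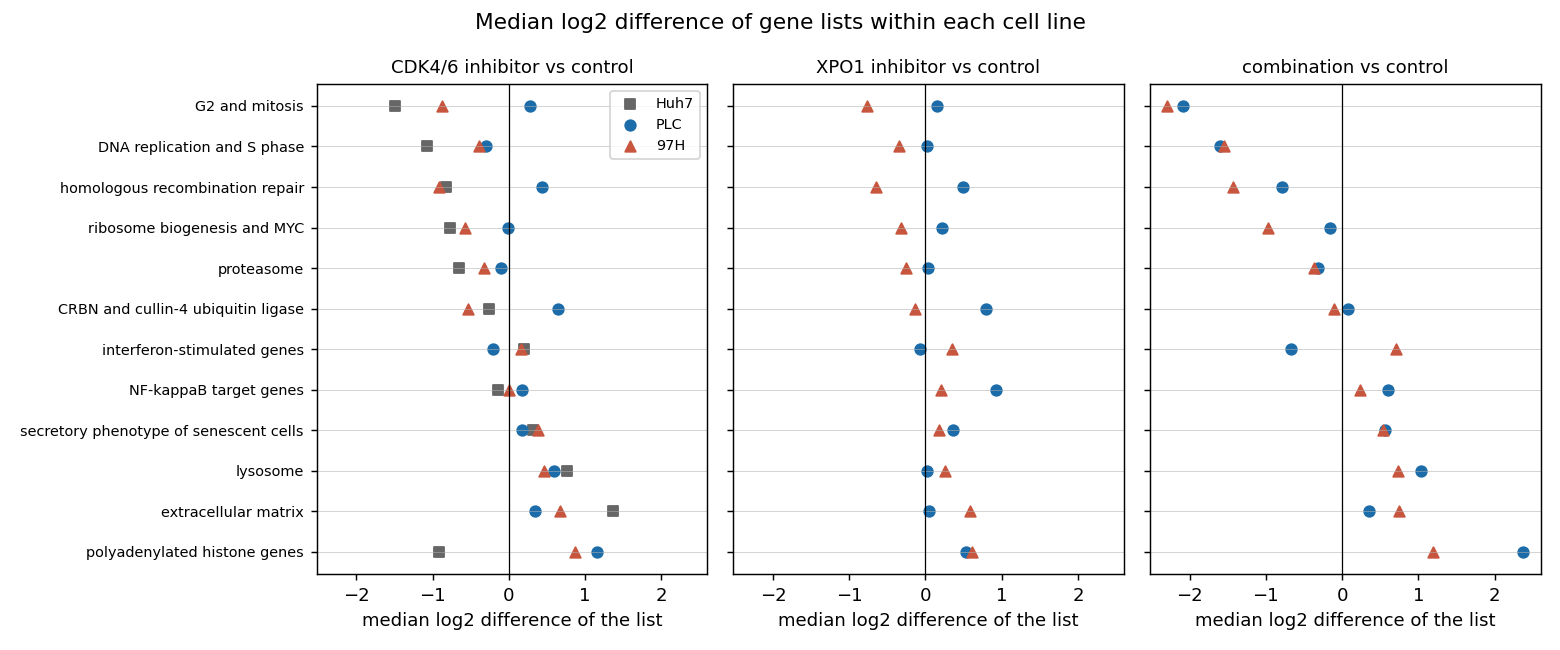
Median log2 difference of gene lists from the control of the same line, 1 point per list and line, in 1 panel per treatment. G2 and mitosis lies at -2.09 in PLC and -2.29 in 97H with the combination, and at 0.27 in PLC (-0.14 after removal of the GC content and length trends) and -0.88 in 97H with the CDK4/6 inhibitor.

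Smaller shifts under the combination were called down by camera for 3 further lists, but not seen in each line. Among random lists matched on expression, oxidative phosphorylation lay at percentile 8.86 in PLC and 55 in 97H. Nuclear transport lay at 82.3 and 0.01, and hypoxia and glycolysis at 0.71 and 38.9. Nuclear genes of oxidative phosphorylation, with CYC1 at -1.09, had medians of -0.38 in PLC and -0.05 in 97H (camera, adjusted p = 0.00249; adjusted p = 0.37 with an estimated correlation). Nuclear transport receptors and Ran, with RCC1 (the Ran exchange factor, -1.39) and KPNA2 (-1.60), had medians of opposite sign, 0.22 in PLC and -0.58 in 97H (camera, adjusted p = 0.00662; adjusted p = 0.423 with an estimated correlation). In that list 1 member fell when adjusted over the list alone, and the PLC median was -0.02 after removal of the GC content and length trends. Hypoxia and glycolysis genes had medians of -0.44 in PLC and -0.06 in 97H, -0.44 and -0.19 after removal of the trends (camera, adjusted p = 0.0177; adjusted p = 0.37 with an estimated correlation), with TPI1 at -1.16 and ADM at 1.51. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 2.19 (adjusted p = 0.0461), from 4.19 to 39.38 FPKM in PLC and from 26.02 to 71.26 FPKM in 97H. Lists that camera did not call include CRBN and cullin-4 ubiquitin ligase (adjusted p = 0.883, COPS6 at -0.67), integrated stress response (0.113, PPP1R15A at 1.53), antigen presentation by MHC class I (0.109, HLA-B at 1.32) and hepatocyte function (0.0855, AFP at -1.41). The same holds for interferon-stimulated genes (0.974), cholesterol synthesis (0.976), heat shock (0.976), endoplasmic reticulum chaperones (0.61) and the target and reference genes (0.61). For the CRBN, interferon, heat shock and chaperone lists the median and the mean lie above 0 while camera has the list down, the median of all genes being 0.071, and for the target genes the median is above 0 and the mean below it. The hepatocyte list had medians of opposite sign, -0.69 in PLC and 0.19 in 97H (-0.47 and 0.20 after removal of the trends). Among random lists matched on expression these lay at percentiles 0 and 95.1. The mitochondrially encoded list has no member in the table.

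Cell-cycle genes were lower with the combination than with either inhibitor, although no single gene passed. Against the CDK4/6 inhibitor, BIRC5 was at -3.02 (SE 0.37, adjusted p = 0.0674, n = 2 lines). MYBL2 was at -3.07, RRM2 at -3.09, UBE2C at -2.40, PLK1 at -2.43, KIF2C at -2.66, CDCA8 at -2.13, FOXM1 at -2.28, TYMS at -2.59 and CDCA3 at -2.23. DUSP15 was at 3.24, PPDPF at 1.90, TRPM4 at 2.39, and CAPN5 (a calpain) at 1.83. DDAH2 was at 1.52, ATP6V0D2 (a proton pump subunit) at 1.72, SDC4 (syndecan 4) at 1.32, SLC43A2 at 2.21, NGFR at 2.62 and MDK (midkine) at 1.25. limma called 0 genes, with 345 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0674. When adjusted over the list alone, 22 of 30 genes of G2 and mitosis fell (camera, adjusted p = 4.02e-55; adjusted p = 0.121 with an estimated correlation) and 27 of 41 of DNA replication and S phase (camera, adjusted p = 1.01e-47; adjusted p = 0.0683 with an estimated correlation). After removal of the GC content and length trends 51 genes passed, 8 up and 43 down, 8 passed with a pseudocount of 0.1 or with quantile normalization, 5 with median ratio scaling and 3 with all 10 libraries in the model. Without the PLC XPO1 inhibitor library 5 passed, without the 97H one 8, and without the 97H CDK4/6 inhibitor library 3.

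Against the XPO1 inhibitor the combination again had lower cell-cycle genes, with BIRC5 at -2.84 (SE 0.37, adjusted p = 0.115, n = 2 lines). RRM2 was at -3.09, PLK1 at -2.54, TYMS at -3.07, KIF2C at -2.67, UBE2C at -2.06, MYBL2 at -2.33, LMNB1 at -2.74, CENPA at -2.53 and FOXM1 at -2.22, none passing. On the upper side stood TMEM140 at 2.01, HIST1H1C (a linker histone) at 1.50, GLMP at 1.28, PCSK1N at 1.78 (1.14 after removal of the GC content and length trends) and HIST1H2AE at 2.12. Next came TP53INP2 (an autophagy factor) at 1.74, the lysosomal sialidase NEU1 at 1.19, CHPF at 1.61, FAM102A at 1.51 and APOE at 1.30. limma called 0 genes, with 520 at an unadjusted p under 0.05. Adjusted over the list alone, 30 of 41 genes of DNA replication and S phase fell (camera, adjusted p = 4.83e-45; adjusted p = 0.0738 with an estimated correlation), as did 27 of 30 of G2 and mitosis (camera, adjusted p = 1.2e-44; adjusted p = 0.16 with an estimated correlation). Histone genes with polyadenylated transcripts were higher, 5 of 12 rising when adjusted over the list alone (camera, adjusted p = 1.58e-10; adjusted p = 0.217 with an estimated correlation). After removal of the GC content and length trends 63 genes passed, 2 up and 61 down, and 4 passed with quantile normalization. Without the PLC CDK4/6 inhibitor library 5 passed and without the 97H one 6.

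The departure of the combination from the sum of the single effects was largest in size for RRM2 at -2.66, TYMS at -2.36, KIF2C at -2.31 and BIRC5 at -2.23 among the 10 lower genes named, none passing. MYBL2 at -1.99, KIF20A at -1.94, CENPA at -1.91, UBE2C at -1.71, PLK1 at -1.70 and TK1 (thymidine kinase) at -1.56 make up the rest. On the upper side POLR2J3 was at 1.71, SLC16A13 at 1.33, PCSK1N at 1.28, ADAMTSL4 at 1.16, PCDH1 at 1.10, APOE at 1.05, FAM229A at 0.99, IER5L at 0.99, PTPRCAP at 0.85 and MDP1 at 0.75. limma called 0 genes, with 60 at an unadjusted p under 0.05. Of 30 genes of G2 and mitosis 11 passed on the lower side when adjusted over the list alone (median -2.36 in PLC, -0.66 in 97H; camera, adjusted p = 8.25e-38; adjusted p = 0.206 with an estimated correlation). Hepatocyte function and cholesterol synthesis lay on the upper side (camera, adjusted p = 1.14e-07 and 3.6e-06; adjusted p = 0.419 and adjusted p = 0.386 with an estimated correlation), with SERPINA1 at 0.72 and MVD at 1.14. Their medians were 0.84 and 0.63 in PLC and 0.08 and 0.08 in 97H, where removal of the GC content and length trends brought cholesterol synthesis to 0.30 (0.47 in PLC). The departures followed GC content, with a rho of 0.804 in PLC and -0.66 in 97H. Random lists matched to G2 and mitosis on expression, GC content and length had medians of -0.90 and 0.27, and after removal of the trends the list was at -1.91 and -0.76. Removal also lowered, by over 1.5 times, ADAMTSL4 (0.77), APOE (0.51), FAM229A (0.46), IER5L (0.51), MVD (0.66), PCSK1N (0.58) and PTPRCAP (0.41).

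With the CDK4/6 inhibitor alone, replication genes were lower and matrix and lysosomal genes higher in the mean of the 3 lines, but no gene passed. TMEM140 was at 1.92 (SE 0.30, adjusted p = 0.461, n = 3 lines), MFGE8 (a secreted glycoprotein) at 1.85, TP53INP2 at 1.68, TIMP2 at 1.63 and MATN3 (a matrix protein) at 1.53. SYNPO (an actin-associated protein) was at 1.49, CYR61 at 1.35, S100A1 at 1.29, the membrane metalloproteinase MMP14 at 1.24 and KCNK6 (a potassium channel) at 1.12. FBL was at -1.24, the transcription factor ETV4 at -1.34, CDCA7 at -1.30, the helicase subunit MCM7 at -1.29 and FKBP4 (an HSP90 co-chaperone) at -1.15. Then followed CENPV at -1.10, the histone chaperone SSRP1 at -1.09, PTMA at -1.003, DDX39A at -0.96 and PA2G4 at -0.93. Of 41 genes of DNA replication and S phase 12 fell when adjusted over the list alone, MCM7, GINS2 (-1.50) and MCM2 (-1.03) leading (camera, adjusted p = 2.96e-16; adjusted p = 0.241 with an estimated correlation). G2 and mitosis genes, PLK1 at -1.20 and PTTG1 at -1.09 leading, had medians of -1.49 in Huh7, 0.27 in PLC and -0.88 in 97H (camera, adjusted p = 1.82e-14; adjusted p = 0.332 with an estimated correlation), and none passed when adjusted over the list alone. After removal of the GC content and length trends the PLC median was -0.14, on the side of the other lines. Matrix genes rose in 5 of 21 cases and lysosomal genes in 9 of 32 when adjusted over the list alone (camera, adjusted p = 1.37e-12 and 4.47e-12; adjusted p = 0.219 and adjusted p = 0.241 with an estimated correlation), with HSPG2 (perlecan) at 1.51 and NEU1 at 0.93. limma called 0 genes, with 922 at an unadjusted p under 0.05. Without the PLC line 747 genes passed, from 1 residual degree of freedom and a common spread, and without the 97H line 1 passed, TTR (transthyretin), singled out after its values were seen.

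With the XPO1 inhibitor alone, CYR61 was at 2.73, the largest value among the 10 higher genes named (SE 0.32, adjusted p = 0.17, n = 2 lines), from 37.58 to 267.5 FPKM in PLC and from 8.967 to 62.06 FPKM in 97H, and no gene passed. DUSP15 was at 2.36, CTGF at 2.31, MYL9 at 2.13, PPDPF at 1.88, the kinase gene PIM1 at 1.57, the autophagy gene GABARAPL1 at 1.48, DDAH2 at 1.36, MDK at 1.33 and SDC4 at 1.27. BHLHA15 (a secretory cell transcription factor) was at -1.73, NPM3 at -1.48, the ribosome assembly gene BOP1 at -1.30 and PHB2 (prohibitin 2) at -1.24. The others were GPAA1 at -1.22, BATF3 at -1.22, SERPINA1 (alpha-1 antitrypsin) at -1.13, TNFRSF6B (a decoy receptor) at -1.09, SDF2L1 at -1.07 and EEF1AKMT4 at -0.87. Hepatocyte genes had a median of -1.07 in PLC and -0.0021 in 97H (0.05 after removal of the GC content and length trends), with FGA (fibrinogen) at -1.22 and APOA2 at -1.81 over both lines, and 1 of 26 fell when adjusted over the list alone (camera, adjusted p = 3.82e-08; adjusted p = 0.397 with an estimated correlation). Cholesterol synthesis genes were lower, DHCR7 at -1.04 and INSIG1 at -0.82 leading, and NF-kappaB target genes higher, CXCL1 at 1.34 and BIRC3 at 1.25 (camera, adjusted p = 3.67e-05 for both; adjusted p = 0.397 with an estimated correlation for both). G2 and mitosis genes had a median of 0.15 in PLC and -0.76 in 97H (-0.12 and -0.70 after removal of the trends). DNA replication and S phase had 0.02 and -0.345 (-0.15 and -0.40), and homologous recombination repair 0.50 and -0.65 (-0.03 and -0.53). In 97H these 3 medians lay at percentile 0 of random lists matched on expression, GC content and length. In PLC they lay at 0.39, 8.13 and 22.4. limma called 0 genes, with 258 at an unadjusted p under 0.05, and the median of all genes was at 0.0954, against -0.0103 after quantile normalization. After removal of the GC content and length trends 1 gene passed, PPDPF; 1 passed with quantile normalization, CYR61, and 1 with no filter on low genes, HIST1H3I, singled out after its values were seen. CYR61 also passed without the PLC CDK4/6 inhibitor library and without the 97H one, the count then being 1.

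Among the drug targets and senescence genes, CDKN1A rose and LMNB1 and CDKN2C (p18, an inhibitor of CDK4 and CDK6) fell with the combination, CDKN2C by 2.68 (adjusted p = 0.0345). MKI67, a proliferation marker, was at -1.96 (adjusted p = 0.0876) and CDKN2B (p15) at 2.28 (adjusted p = 0.0918). Differences from control with the combination, in PLC and then 97H, were 0.99 and 0.42 for XPO1 and -0.26 and 0.53 for CRBN. They were -0.10 and -0.12 for DDB1, 1.13 and -0.43 for CUL4A, 0.01 and 0.13 for RBX1 and -0.03 and -0.42 for VHL, parts of the ubiquitin ligases that degrader drugs recruit. The kinases and cyclins had -1.05 and -0.32 for CDK4, 0.66 and -0.12 for CDK6, 1.54 and 0.59 for CCND1 (cyclin D1), -0.21 and 0.10 for CCND3, 0.22 and 0.21 for RB1, -0.80 and -0.10 for CCNE1 and -0.72 and -0.84 for E2F1. CDKN1B (p27) was at -0.34 and -0.45, CDKN2A (p16) at -0.35 and 0.56, HMGB2 at -0.33 and -0.47, GLB1 (the lysosomal beta-galactosidase) at 0.58 and 0.94 and MYC at 0.28 and -0.53, none passing. Under the combination, removal of the trends turned the sign of CDKN2A (0.22) and CCND3 (0.07) in PLC and of CDK6 (0.05) in 97H, and brought CDK6 in PLC to 0.28. It also moved, by over 1.5 times, E2F1 (-0.35), CRBN (-0.44), CUL4A (0.68), RBX1 (0.09), VHL (-0.34), CDKN1B (-0.52) and MYC (0.46) in PLC. In 97H it did so for DDB1 (-0.07), CUL4A (-0.23), RBX1 (0.22), VHL (-0.23), CCND3 (0.03), CCNE1 (-0.06), CDKN1B (-0.27) and CDKN2A (0.23). RBL1, CCNE2 and CCND2 were under the filter, at means of 0.99, 0.68 and 0.0053 FPKM. With the CDK4/6 inhibitor, CDKN1A was at 1.26 in Huh7, 1.50 in PLC and 0.75 in 97H (0.41 after removal of the trends), and CRBN at -0.18, 0.38 and -0.43. After removal of the GC content and length trends CRBN was at 0.02, -0.19 and 0.08, so its sign turns in each line. LMNB1 was also lower with the CDK4/6 inhibitor, at -2.21 in Huh7, -0.40 in PLC and -1.22 in 97H. CDKN2C was at -1.97, -0.86 and -1.21 (-0.295 in PLC after removal of the trends) and HMGB2 at -2.66, 0.18 and -1.59. With the XPO1 inhibitor LMNB1 was at 0.505 in PLC and -0.82 in 97H. CDKN2C was then at 0.07 (0.65 after removal of the trends) and -1.25, and HMGB2 at 2.07 and 0.465. XPO1 was at 2.35 in PLC and 0.25 in 97H with the XPO1 inhibitor (1.66 and 0.51 after removal of the trends), and did not pass over both lines.

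The lines differed in the size and the pattern of their responses, described here without a test. With the CDK4/6 inhibitor 2463 genes of PLC, 864 of Huh7 and 668 of 97H differed from control by at least 1 on the log2 scale. It was 2363 of PLC and 279 of 97H with the XPO1 inhibitor, and with the combination 2026 of PLC and 1319 of 97H. Removal of the GC content and length trends brought PLC to 1111 and 97H to 162 with the CDK4/6 inhibitor and PLC to 823 with the XPO1 inhibitor. A pseudocount of 0.1 put Huh7 at 1409 and 97H at 1626 with the CDK4/6 inhibitor, which turns their order, and 97H at 689 with the XPO1 inhibitor and 1999 with the combination. With a filter of 5 FPKM, which tests fewer genes, PLC had 1561 with the CDK4/6 inhibitor. All counts of a line rest on its 1 control library. As deposited, the PLC combination library differed by at least 1 from the PLC CDK4/6 inhibitor library in 921 genes. It differed from the PLC XPO1 inhibitor library in 1154. In 97H these counts were 825 and 448. Across genes, which are not independent replicates, the CDK4/6 inhibitor differences of PLC and 97H had a Spearman rho of -0.512, those of Huh7 and 97H 0.418, and the combination differences of PLC and 97H 0.197. The differences also followed the GC content of the transcripts: rho with GC content was -0.677 in PLC, 0.723 in 97H and 0.177 in Huh7 for the CDK4/6 inhibitor, and -0.72 in PLC for the XPO1 inhibitor. GC content and length account for part of the variance of each library's log2 deviations from the gene means over the 10 libraries. The share is 12.3% in the PLC control library, 12.2% in PLC with the CDK4/6 inhibitor and 12.9% in PLC with the XPO1 inhibitor. It is 12.7% in 97H with the CDK4/6 inhibitor, against 1.54% to 2.63% in the other 6 libraries. The 521 genes of lowest GC content had a median CDK4/6 inhibitor difference of 0.82 in PLC and -0.51 in 97H, and the 521 of highest GC content -0.58 and 0.46. After removal of these trends the rho between PLC and 97H was -0.000552 for the CDK4/6 inhibitor, and it turned from -0.271 to 0.112 for the XPO1 inhibitor.

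**Figure D3:**
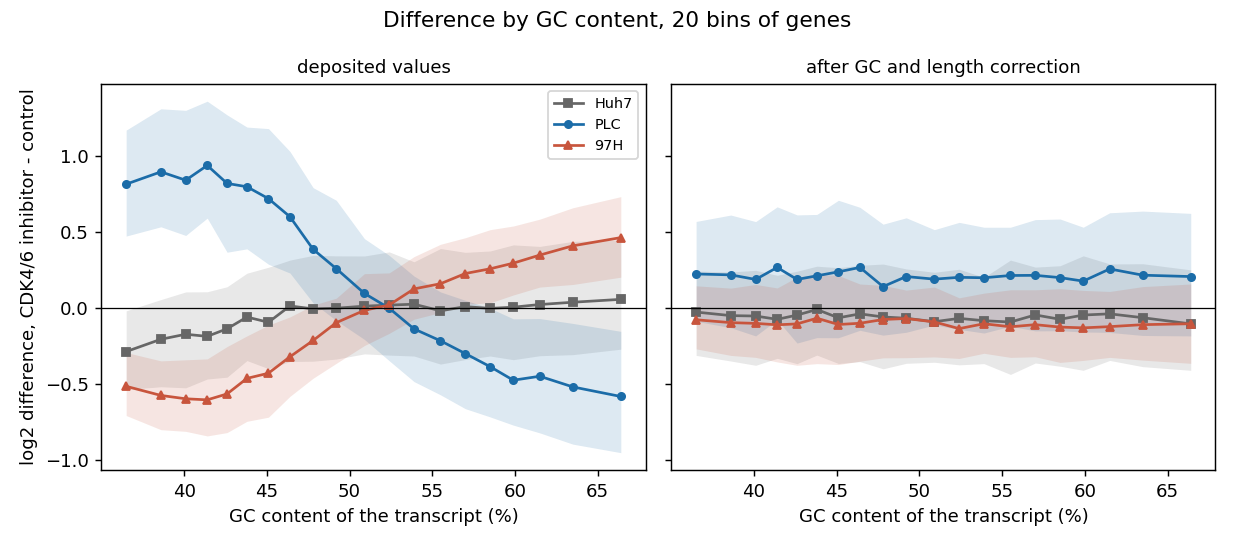
Median log2 difference of the CDK4/6 inhibitor library from control in each line (points) with the quartiles (shading), against the GC content in percent of the transcripts in 20 groups of genes, as deposited and after removal of the GC content and length trends. As deposited, the group of lowest GC content lies at 0.82 in PLC and -0.51 in 97H and that of highest at -0.58 and 0.46.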

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

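All tests of explanations in this part were chosen after the results were seen. Several target genes and gene lists differed between lines in opposite directions, by at least 0.5 on the log2 scale on either side of 0. None of these differences was tested, with 1 library per line and treatment. With the CDK4/6 inhibitor, CDK6 was at 1.76 in PLC and -0.59 in 97H, a gap of 2.35 (1.02 and -0.17 after removal of the GC content and length trends). XPO1 was at 1.16 in PLC and -1.34 in 97H, a gap of 2.5 (0.44 and -0.85 after removal). CUL4A, the cullin scaffold of the CRBN ligase, was at 1.34 and -0.66, a gap of 2.01 (0.63 and -0.22). RB1 was at 1.13 in PLC and -0.61 in Huh7, a gap of 1.75 (0.47 and -0.43). RBX1 was at 0.57 and -0.63, a gap of 1.21 (0.52 and -0.47). Among lists, the median of CRBN and cullin-4 ubiquitin ligase was 0.65 in PLC and -0.54 in 97H, a gap of 1.19 (0.35 and -0.28 after removal of the trends). That of endoplasmic reticulum chaperones was 0.63 and -0.54, a gap of 1.17 (0.25 and -0.53). Nuclear transport receptors and Ran had 0.71 in PLC and -0.68 in Huh7, a gap of 1.39 (0.17 and -0.77 after removal of the trends). Histone genes with polyadenylated transcripts had 1.16 and -0.92, a gap of 2.08 (1.19 and -0.80 after removal of the trends).

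With the XPO1 inhibitor, LMNB1 was at 0.51 in PLC and -0.82 in 97H, a gap of 1.33 (0.23 and -0.79 after removal of the trends). Endoplasmic reticulum chaperones had medians of 0.56 and -0.55, a gap of 1.10 (0.30 and -0.59). With the combination, interferon-stimulated genes had a median of 0.71 in 97H and -0.68 in PLC, a gap of 1.39 (0.78 and -0.57 after removal of the trends). Endoplasmic reticulum chaperones had 0.82 in PLC and -0.60 in 97H with the combination, a gap of 1.42 (0.49 and -0.45 after removal).

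The opposite responses of PLC and 97H to the CDK4/6 inhibitor (Spearman rho -0.512 across genes) may come from GC content and length trends that differ between libraries. Among the 1042 genes of middle GC content, 48.4% to 51.7%, the rho was -0.148, weaker than over all genes. Low depth predicts that the relation fades among well-expressed genes. Among the 2937 genes with a mean of at least 20 FPKM the rho was -0.303, also weaker than over all genes. The GC content and length trends were left in these values, so this test cannot tell depth from the trends. An opposite response that does not follow GC content predicts that the relation outlasts the correction, and after it the rho was -0.000552. A response that itself follows GC content stays open, since no line and treatment has a second library.

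XPO1 mRNA stood at 48.32 FPKM in PLC with the XPO1 inhibitor against 8.655 FPKM in its control, a log2 difference of 2.35. GC content and length are an unlikely source: XPO1 lay at percentile 99.5 of the 200 genes nearest in both, and removing the trends left a difference of 1.66. Scaling is unlikely as well, the median of all genes in PLC being 0.144. Against the same PLC control, XPO1 was at 1.16 with the CDK4/6 inhibitor and 0.99 with the combination. After removal of the trends these were 0.44 and 0.71. How much of the 2.35 comes from that 1 control library was not tested. A response of the XPO1 transcript in both lines remains a hypothesis: XPO1 lay among the top 2.5% of those nearest genes in 2 of the 4 libraries given the inhibitor, those of PLC and 97H with it alone, but at percentiles 87.5 and 88.5 with the combination. In 97H with the inhibitor alone it was at 0.25, and at 0.51 after removal of the trends. Whether the transcript responds in both lines or in PLC only cannot be told apart from these libraries.

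For the CDK4/6 inhibitor against control, the 6 libraries of 3 lines make 10 splits, too few for a share under 0.05. The real split gave 0 genes with limma, a count that all 10 splits reach by construction, and the highest of the others gave 4. As the line pairs the libraries, the real split belongs with the 3 others that part the libraries of each line, and these also gave 0 genes. At an unadjusted p under 0.05 the real split had 922 genes and these 3 had 1183, 1992 and 40. After removal of the GC content and length trends they had 1668 against 755, 986 and 100. The remaining 6 splits put both libraries of a line on the same side, among them the one with 4 genes, which holds both Huh7 libraries and the PLC control (2395 at an unadjusted p under 0.05).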

How the results depend on the processing

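The correction for GC content and length, its repeats and the filter over 8 libraries were chosen after the results were seen. The cause of a change was not tested except where stated. Where 1 of the 8 libraries of PLC and 97H is left out, its treatment keeps 1 library. The spread in such a fit comes from the other treatments. The combination against control, 83 genes, had 1 gene with no filter (HIST1H3I), 153 with quantile scaling, 0 without the line as a block, 261 with all 10 libraries and 27 with a single prior variance. Correction for GC content and length gave 576, and for GC content alone 471. With the correction there were 246 without the PLC control and 488 without the 97H CDK4/6 inhibitor library. Of the 83, all 83 were called with the correction and with quantile scaling, and 53 without the 97H control. Leaving out 1 library gave 0 to 184 genes: 0 without the PLC control or the PLC combination, 2 (BIRC5, TYMS) without the 97H combination, 158 without the PLC CDK4/6 inhibitor, 166 without the 97H control and 184 without the 97H CDK4/6 inhibitor. The CDK4/6 inhibitor against control had 0 genes by limma (922 at an unadjusted p under 0.05), and 0 to 747 with a line left out (747 without PLC, 1 without 97H). It had 1 with the correction and no 97H CDK4/6 inhibitor library (TMEM140). The XPO1 inhibitor against control had 1 with no filter, 1 with quantile scaling, and 1 with the correction. It had 1 with the correction and no PLC control (SPINK1, singled out after its values were seen), and 3 with it and no 97H CDK4/6 inhibitor library (CYR61, DUSP15, PPDPF). It had 0 to 1 with 1 library left out, 1 without the PLC or 97H CDK4/6 inhibitor. The combination against the CDK4/6 inhibitor had 8 with a pseudocount of 0.1, 8 with quantile and 5 with median ratio scaling, 3 with all 10 libraries, and 6 with the filter over 8 libraries. It had 51 with the correction, 42 for GC content alone, 94 with it and no PLC control, and 1 with it and no 97H CDK4/6 inhibitor library. It had 0 to 8 with 1 library left out (5 without the PLC XPO1 inhibitor, 8 without the 97H one, 3 without the 97H CDK4/6 inhibitor). The combination against the XPO1 inhibitor had 4 with quantile scaling, 63 with the correction, 44 for GC content alone, and 93 and 43 in its repeats. It had 0 to 6 with 1 library left out (5 and 6 without the PLC and the 97H CDK4/6 inhibitor). The interaction stayed at 0 by limma, from 60 at an unadjusted p under 0.05, under each setting run other than the fit without PLC given below. List tests called 73 at the preset correlation, 0 with it estimated, and 3 (directional) and 18 (mixed) with fry. The rho between lines moved with the correction only, for the CDK4/6 inhibitor from 0.146 to 0.353 (Huh7 and PLC) and from -0.512 to -0.000552 (PLC and 97H). It moved for the combination from 0.197 to 0.377, and it reversed for the XPO1 inhibitor from -0.271 to 0.112. Genes differing by at least 1 within a line went, with a pseudocount of 0.1, to 1409 in Huh7 and 1626 in 97H with the CDK4/6 inhibitor and to 689 and 1999 in 97H with the XPO1 inhibitor and the combination. In PLC with the CDK4/6 inhibitor they went to 1561 with a filter of 5 FPKM. With the correction they went to 1111 in PLC and 162 in 97H with the CDK4/6 inhibitor and to 823 in PLC with the XPO1 inhibitor. Of 262 values of named genes, no call turned direction under the settings run. Under the correction 217 kept direction and side of the threshold, 33 passed that had not, and 12 that passed under neither changed sign. Without the block 22 lost their call. Of the 73 list calls, 68 held with the correction, 65 with quantile scaling and 61 without the block, but 0 with the correlation estimated, 3 with fry's directional and 12 with its mixed p. Of the 12 for the CDK4/6 inhibitor against control, 10 held without Huh7, 10 without PLC and 7 without 97H. With a line left out of the 8 libraries, the XPO1 inhibitor, combination and interaction fits could not be made, as no residual degrees of freedom remain. With Huh7 kept in the model 1 remains, but each of these treatments then has 1 library, and the spread comes from the CDK4/6 inhibitor effect in the lines kept. Without PLC and without 97H, such fits gave 69 and 6 genes for the XPO1 inhibitor and 1065 and 54 for the combination against control (82 and 33 of the 83). They gave 339 and 4 for the combination against the CDK4/6 inhibitor, 112 and 3 against the XPO1 inhibitor, and 8 and 0 for the interaction; these fits were added after the results were seen. A count test was not run, as whole reads were not recoverable. The absolute depth of the libraries is unknown, so genes at 0 FPKM are below detection rather than absent.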

Other observations

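The test of each explanation in this part was chosen after the results were seen. Some markers of other cell types were under 0.5 FPKM in each library: PTPRC (leukocytes) reached 0.0226 FPKM, CD3E (T cells) 0.035, DCN (fibroblasts) 0.114, HBB (red cells) 0.198, VWF and CDH5 (endothelium) 0.349 and 0.304, and KRT5 (basal epithelium) 0. Other markers were measured at higher levels, PECAM1 up to 4.22 FPKM in the 97H combination library, and PDGFRB, ACTA2 and CD14 up to 4.34, 2.24 and 2.13 in Huh7 with the CDK4/6 inhibitor. So were KRT19 up to 634 FPKM and KRT7 up to 34.6 in the 97H combination library, LYZ up to 234 in PLC with the XPO1 inhibitor and LUM up to 40.8 in Huh7 with the CDK4/6 inhibitor. Huh7 under the CDK4/6 inhibitor alone had lower cell-cycle genes, with list medians of -1.49 for G2 and mitosis and -1.08 for DNA replication and S phase. Across genes, which are not independent replicates, its differences had a Spearman rho of 0.404 with those of PLC and 0.459 with those of 97H under the combination. Under the CDK4/6 inhibitor the rho of Huh7 was 0.146 with PLC and 0.418 with 97H. Removal of the GC content and length trends gave 0.46 and 0.488 for the combination and 0.353 and 0.464 for the CDK4/6 inhibitor.

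Cell-cycle genes lower with the combination than with either inhibitor could stem from GC content and length trends that differ between libraries, but the highest percentile of the 8 list medians (2 lists, 2 lines, 2 comparisons) among random lists matched on expression, GC content and length was 0. A single aberrant combination library is unlikely, as the weakest of the 8 medians was -1.21. An effect beyond the sum of the single effects remains a hypothesis: the G2 and mitosis list had a median interaction of -2.36 in PLC and -0.66 in 97H (-1.91 and -0.76 after removal of the trends), with adjusted p = 0.206 with an estimated correlation. Such an effect and a sum of single effects cannot be told apart from these libraries.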
